A study of Mus musculus with 12 samples.

How the data were processed

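Pituitaries of newborn mice without the posterior lobe were sequenced as 12 libraries, 6 per group. Per the labels' protocols, total RNA was extracted with an Ambion micro kit and libraries were made with the TruSeq RNA kit v2, which keeps no strand. Per the submitters' processing notes, the tools were FastQC 0.10.1, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks and Cuffdiff 2.1.1, with the genome build mm10. Samples were grouped by the genotype in their labels. The series design calls them individual samples, and p-values measure the spread between these samples.

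The deposited per-library table holds 27129 genes with estimated counts of fragments (headed raw fragments) and FPKM for each library, per the file headers. Exactly whole values made up 89.99% to 90.41% of the non-zero counts of a library, and the rest were rounded to whole numbers. A further 12 columns of scaled fragments were not used. The authors' deposited comparison table gives an FPKM per group, the log2 fold change and a q-value. Per the file headers, the authors marked genes with q of at most 0.05 and a fold of at least 1.5. The authors' deposited enrichment table gives a fold enrichment (a ratio) and a Benjamini-adjusted p-value per term from DAVID. GO terms could not serve as a background for other tests, because the 633 genes with GO terms in the deposited gene table are all genes the authors marked.

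Genes with FPKM of at least 1 in at least 6 of the 12 libraries were tested, which left 15246 and set aside 11883. The test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with TMM scaling and no covariate, with Benjamini-Hochberg adjusted p under 0.05. The design written before the data were examined had limma on log2(FPKM + 1) and foresaw edgeR if the files held counts, so edgeR replaced it and limma 3.58.1 became an alternative. Standard errors were derived from the log2 fold change and the F statistic. Values are TMM-scaled CPM (fragments of a gene relative to the scaled library total) with the SD over libraries. FPKM served for the filter, the limma alternatives and the Y-linked covariate (mean of log2(FPKM + 1) over 4 Y-linked genes). The FPKM of control 0 and mutant 0 relate to their counts differently from those of the other libraries.

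Gene lists were fixed before the data were examined: 31 lists, of which 30 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 30 lists. The genes to name were also set before: Isl1, the 10 largest log2 fold changes in each direction among called and fully separated genes with mean FPKM of at least 5 in a group, all 7 hormone genes, 8 pituitary regulators (1 of them is not reported here), and up to 4 members of each list with the smallest adjusted p. The 10 largest excluded predicted and clone names, Y-linked genes and Xist. Without the regulator not reported, this rule gave 132 genes. A limit set after their values were seen kept list members only where called, which left 70 that the text may name.

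The tests were checked on simulated counts for 15246 genes with the library sizes of this comparison. With 50 genes at each fold, edgeR called 46% at a fold of 1.25, 94% at 1.5, 94% at 2 and 96% at 4, and called 14 of 15046 unchanged genes. The exact Wilcoxon test called 0% at every fold, an outcome fixed in advance, because with so few changed genes its smallest possible p cannot pass the adjustment. The shallowest library held 45415453 fragments. Pairs of replicates of a group differed by more than sampling noise (chi-square per degree of freedom 15.4 to 38.8 over 30 pairs), so no library was counted as a duplicate.

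The alternatives were other pseudocounts, filters, scalings, covariates and prior variances, array weights, a fold minimum, the Wilcoxon test, DESeq2 1.42.0, the replicate number as a block, and leaving out each of the 12 libraries in turn. Chosen after the data were seen were DESeq2, edgeR's own filter, and fits without the 3 libraries with high Xist or without both libraries numbered 0. Figures were drawn with matplotlib 3.10.9.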

Results

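Gene expression was measured by RNA sequencing in pituitary glands of newborn mice (postnatal day 0) from which the posterior lobe had been removed. There were 12 libraries, which the series design describes as individual samples. The 6 control glands carried a transgene that drives Cre recombinase in pituitary progenitors, with 1 floxed and 1 intact allele of Isl1. The 6 other glands carried the same transgene with 1 floxed and 1 null allele of Isl1, and are called mutant in the labels. Control libraries held 46204920 to 51535425 fragments and libraries labelled mutant held 45415453 to 61533576. The gene for growth hormone, Gh, took between 3.87% and 5.35% of the fragments of a library. The 1 comparison of the design asks which genes differ between these groups after Isl1, a LIM-homeodomain transcription factor, is deleted in pituitary progenitors.

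The targeted gene was examined first, as a possible check of the labels. Isl1 (chromosome 13, 116298270 to 116309688, mm10) was higher in the libraries labelled mutant. The level of Isl1 would have been lower there if the deletion removed its transcripts. Its level was 35.4 ± 3.04 CPM in controls and 59.3 ± 4.98 CPM in the libraries labelled mutant (SD, n = 6 each), a log2 fold change of 0.74 with a standard error of 0.0652 and an edgeR adjusted p of 8.71e-06. Control libraries lay between 31.8 and 40.8 CPM and the others between 53.4 and 68.2 CPM, so that the groups did not overlap. The exact two-sided permutation test over the 924 splits gave p = 0.00216, the smallest value it can give. In the authors' deposited table the FPKM of Isl1 was 14.8 in controls and 24.9 in the mutant group. No other gene of the per-library table overlaps this interval. The values pool all exons of the gene, so they do not show whether the floxed exons were transcribed. The level of the whole gene can therefore neither bear out the labels nor contradict them. For this reason every direction below is that of the libraries labelled mutant over control.

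Among the fixed gene lists, those of motile cilia, stratified epithelium and simple epithelium had the highest median log2 fold changes (0.91, 0.84 and 0.49), and those of gonadotropes, hormone genes and thyrotropes the lowest (-2.30, -0.67 and -0.60). Of 15246 genes tested with edgeR, 656 were higher and 419 lower in the libraries labelled mutant. At a fold of at least 2 the counts were 148 higher and 9 lower, so most of the genes that fell did so by less. Of the 15246 genes tested, the groups were fully separated for 443 with higher and 209 with lower values in the libraries labelled mutant, where chance separates 0.216% of genes. The first principal component held 36.2% of the variance and parted the groups. The number of lower genes moved with the test and with single libraries: it was 216 with limma on log2(FPKM + 1), 807 with DESeq2, 197, 259 and 273 without control 1, 3 or 4, and 237, 211, 239 and 248 without mutant 1, 2, 3 or 4. Higher genes made up 61% of the calls, and 71.3% with scaling to the library total (725 higher, 292 lower) or 70.5% with limma on log2(FPKM + 1) (516 higher). The share was 55.8% with array weights in limma (721 higher, 570 lower), 53.7% with DESeq2 (935 higher, 807 lower) and 72.5% without the 3 libraries with high Xist (379 higher, 144 lower).

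**Figure D1:**
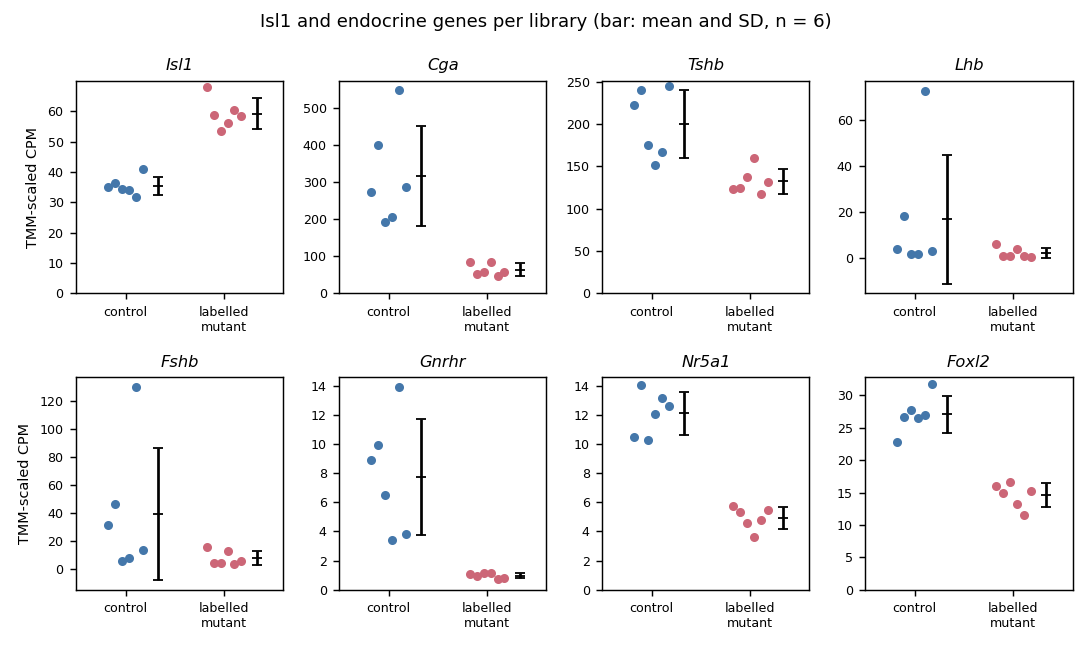
Expression of Isl1 and 7 endocrine genes in each library, as TMM-scaled CPM on linear axes. Each point is 1 library of the control group or of the group labelled mutant, and the black bar is the mean with the SD of 6 libraries. Isl1 lies between 53.4 and 68.2 CPM in the libraries labelled mutant and between 31.8 and 40.8 CPM in controls, while Lhb and Fshb overlap between the groups.

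Among the genes under the naming rule the largest increase was that of Reg3g, which encodes a secreted antimicrobial lectin. It rose from 0.189 ± 0.116 to 14.2 ± 7.41 CPM (SD, n = 6), a log2 fold change of 6.20 with a standard error of 0.466 and an edgeR adjusted p of 3.7e-06. Krt15 and Krt5, keratins of basal cells in stratified epithelia, rose 37.8-fold and 32.0-fold, to 25.7 ± 9.42 and 13.5 ± 4.85 CPM (SD, n = 6). Without control 3, which held 2.099 and 1.317 CPM, the most among controls, the folds were 65.6 and 56.8. Tmem212 rose by 4.94, Dmkn by 3.72 and Msln, the surface glycoprotein mesothelin, by 3.58 on the log2 scale. Cyp2f2, Cbr2 and Sec14l3, all abundant in airway epithelium, rose by 3.61, 3.54 and 3.53. Pglyrp1, a peptidoglycan recognition protein, rose by 3.52. The edgeR adjusted p-values of these 10 genes lay at or below 2.56e-05.

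The fixed list of motile cilia genes rose: 25 of its 30 tested members were higher and 0 lower, and 26 were higher when adjusted over the list alone. The camera adjusted p was 1.7e-31 with the preset correlation, and the adjusted p was 0.0249 with an estimated correlation. Besides Tmem212, Ak7 rose by a log2 fold change of 3.82, Lrrc23 by 2.61 and Ccno, a regulator of centriole amplification in multiciliated cells, by 2.51. The list of stratified epithelium and desmosomes rose likewise, with 15 of 21 members higher, 0 lower and 17 higher adjusted over the list alone (camera adjusted p = 4.3e-20, and adjusted p = 0.0217 with an estimated correlation). Ly6d rose by 4.16, Krt4 by 2.80 and the desmosomal cadherin Dsc3 by 0.87. Of the 22 tested genes of simple epithelium and tight junctions, 14 were higher and 1 lower, or 17 and 1 adjusted over the list alone. Krt19 rose 3.99-fold, and the log2 fold change was 1.57 for the transcription factor Ehf and 0.68 for Krt7. The lower gene, named here after its value was seen, was Wfdc2 at -0.41. This list passed with the preset correlation (camera adjusted p = 2.4e-16), and its adjusted p was 0.0571 with an estimated correlation, so the call was lost. In the list of epithelial stress and inflammation, 3 of 8 tested genes were higher, or 5 adjusted over the list alone (camera adjusted p = 6.9e-06, and adjusted p = 0.0162 with an estimated correlation). Anxa1 rose from 18.1 ± 4.53 to 69.2 ± 17.5 CPM (SD, n = 6), Lcn2, an iron-sequestering lipocalin, by 1.76 and S100a6 by 1.36 on the log2 scale. Of 12 markers of nasal and oral epithelium, chosen after the epithelial result was seen, 5 reached a mean FPKM of 1 in the libraries labelled mutant, among them Ltf at 4.91 against 0.538 in controls and Gnal at 2.61 against 2.44. Bpifa1 was at 3.39 against 0.022 and Muc5b at 1.58 against 0.034, but neither passed the level filter, so they were not tested here. The authors' deposited table marks Muc5b and Muc5ac as higher (log2 fold changes 5.55 and 5.58, Cuffdiff q = 0.0012 each). All markers but Scgb1a1 had a higher mean FPKM than in controls.

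**Figure D2:**
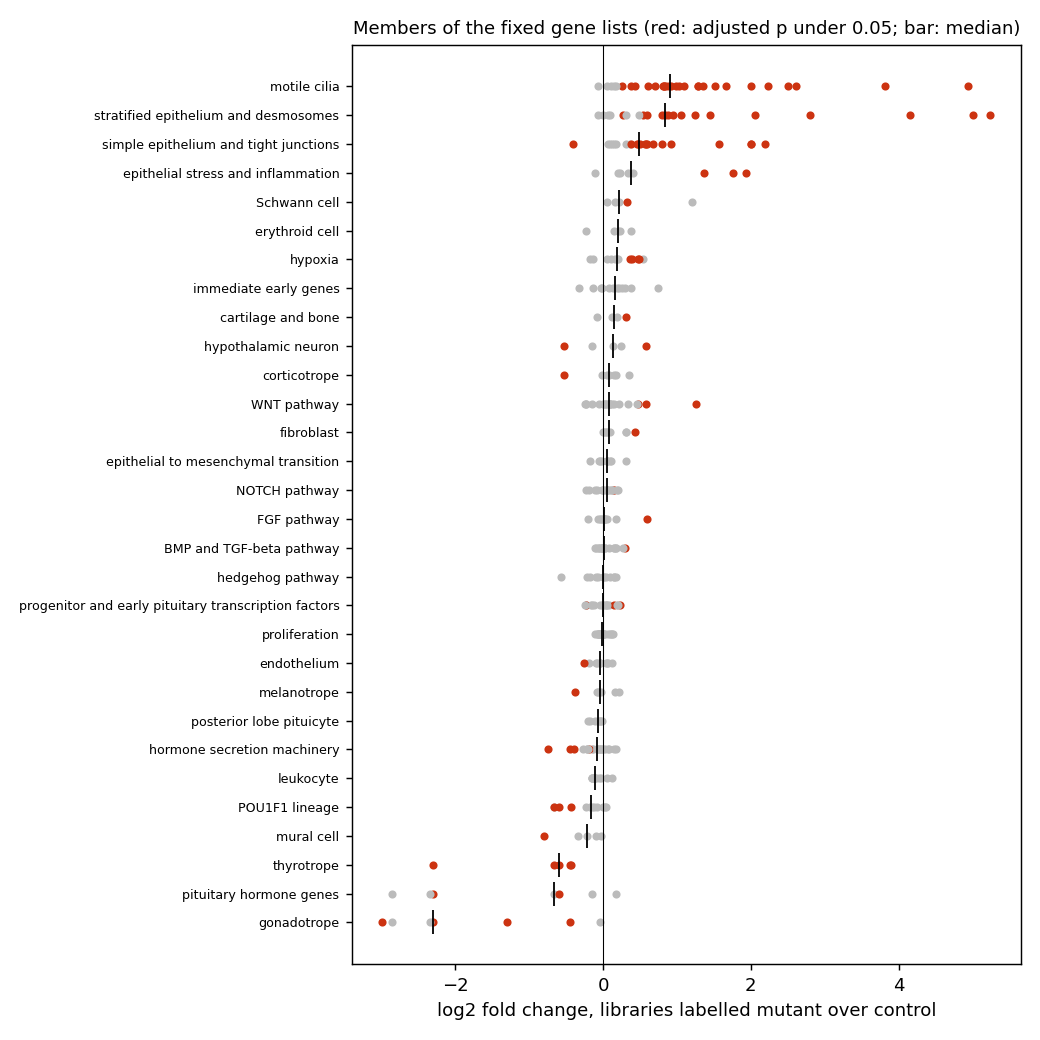
Log2 fold change of each tested member of 30 gene lists, libraries labelled mutant over control, with lists ordered by their median. Each point is a gene, red where the edgeR adjusted p was under 0.05, and the black bar is the median of the list. The medians run from -2.30 for the gonadotrope list to 0.91 for motile cilia.

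Genes of gonadotropes, the cells that make luteinizing and follicle-stimulating hormone, fell. The receptor gene Gnrhr went from 7.75 ± 3.99 to 0.970 ± 0.177 CPM (SD, n = 6), a log2 fold change of -2.99 with a standard error of 0.329 and an edgeR adjusted p of 5.7e-05. Cga, which encodes the subunit shared by the glycoprotein hormones, went from 318 ± 135 to 64.5 ± 16.5 CPM, a log2 fold change of -2.30. Nr5a1, a transcription factor required in gonadotropes, had a log2 fold change of -1.30. In the gonadotrope list 4 of 7 members were lower and 0 higher, or 6 lower adjusted over the list alone (camera adjusted p = 6.9e-07, and adjusted p = 0.0248 with an estimated correlation). The specific subunits Lhb and Fshb did not pass over all genes, though the authors' deposited table marks both (log2 fold changes -2.84 and -2.33, Cuffdiff q = 0.0012 each). Lhb was at 17.1 ± 28.1 CPM in controls and 2.36 ± 2.31 CPM in the libraries labelled mutant (log2 fold change -2.85, edgeR adjusted p = 0.0969), and Fshb at 39.2 ± 47.2 and 7.75 ± 5.18 CPM (log2 fold change -2.34, edgeR adjusted p = 0.0665). The control SD exceeded the control mean for both. The 3 libraries with high Xist and next to no Y-linked transcripts were control 4, mutant 0 and mutant 3, so that the sexes were spread as 1 of 6 controls and 2 of 6 libraries labelled mutant. Control 4 held the highest Lhb, at 72.9 CPM. With the level of Y-linked genes as a covariate the gene Lhb and the gene Fshb passed (edgeR adjusted p = 0.00755 and 0.00725). DESeq2 also called both, with adjusted p = 0.0307 and 0.0189, and Fshb passed without control 2 (edgeR adjusted p = 0.0372) or control 3 (0.0497). Without control 4 their log2 fold changes were -1.33 and -1.44 (edgeR adjusted p = 0.334 and 0.177).

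All 5 thyrotrope genes tested were lower, over all genes and adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.0248 with an estimated correlation). The largest fall among them was that of Cga (-2.30). Cga and Gata2 are also in the gonadotrope list, so the results of these lists are not independent. Tshb, the specific subunit of thyroid-stimulating hormone, went from 200.2 ± 40.5 to 132 ± 14.96 CPM (SD, n = 6; log2 fold change -0.60, edgeR adjusted p = 0.00804). Dio2, which activates thyroid hormone, had a log2 fold change of -0.66 and Gata2 of -0.44. Trhr, the receptor for thyrotropin-releasing hormone, had a log2 fold change of -0.43 and an edgeR adjusted p of 0.0416, which rose to between 0.0732 and 0.0888 without control 0, 1, 2 or 5 or without mutant 0, 1, 4 or 5 and to between 0.0939 and 0.0953 with limma at 4 pseudocounts. Of the 12 POU1F1 lineage genes, 3 were lower and 0 higher, or 4 lower adjusted over the list alone, and these 3 were Tshb, Dio2 and Trhr (camera adjusted p = 0.00235, and adjusted p = 0.128 with an estimated correlation). Of the 7 hormone genes, Cga and Tshb were lower (4 adjusted over the list alone; camera adjusted p = 0.014, 0.0718 on ranks, and adjusted p = 0.331 with an estimated correlation). Gh had a log2 fold change of -0.16, Pomc of 0.18 and Prl of -0.67, with edgeR adjusted p-values of 0.312, 0.307 and 0.597. Control 2 held 17.96 CPM of Prl against 0.929 to 7.93 in the other controls, and without it the gene Prl was at 0.28 (edgeR adjusted p = 0.779). The authors' deposited table marks Prl as lower (log2 fold change -0.67, Cuffdiff q = 0.0012).

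Among the regulators, Pax7, which specifies melanotropes, was lower with a log2 fold change of -0.38 and an edgeR adjusted p of 0.00464. Sox2, a marker of pituitary progenitors, was higher with a log2 fold change of 0.23 and an edgeR adjusted p of 0.0335. That call was lost, at 0.051 to 0.0751, without control 0, 2 or 4 or without mutant 2, 3, 4 or 5, at 0.073 without the 3 libraries with high Xist and at 0.0501 with limma at a pseudocount of 0.1. The Sox2 interval in the file runs from 34104438 to 34682619 on chromosome 3, and the kit kept no strand. Pou1f1, Tbx19 and Neurod4 had log2 fold changes of -0.12, 0.05 and -0.22, with edgeR adjusted p-values of 0.141, 0.839 and 0.210. Without control 5, Pou1f1 passed at -0.15 (edgeR adjusted p = 0.0463). The forkhead factor Foxl2 and its neighbouring transcript Foxl2os were lower, by log2 fold changes of -0.89 and -0.86. The melatonin receptor gene Mtnr1a (-1.14) and the potassium channel genes Kcnk9 (-0.92), Kcnk3 (-0.81) and Kcng1 (-0.74) were lower too.

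The list of hormone secretion machinery had 4 lower and 0 higher members of 22, or 10 lower adjusted over the list alone (camera adjusted p = 0.000276, and adjusted p = 0.402 with an estimated correlation). The granins Chgb, Chga and Scg2 had log2 fold changes of -0.75, -0.45 and -0.39 and Syt7 of -0.19. The call of Syt7 was lost with limma at 4 pseudocounts (adjusted p = 0.0537 to 0.054) and without the 3 libraries with high Xist (edgeR adjusted p = 0.111). In the hypoxia list 4 of 12 genes were higher, or 8 adjusted over the list alone (camera adjusted p = 0.000685, and adjusted p = 0.173 with an estimated correlation). Egln3 rose by 0.48 and Ankrd37 by 0.36. Bnip3 was at 0.47 and lost its call, at 0.0681 to 0.0967, without control 1, 3, 4 or 5 or mutant 1, 2, 3 or 4. Slc2a1 was at 0.39 and lost its call, at 0.0538 to 0.108, without any library but control 2 and mutant 0, and limma at 4 pseudocounts called neither (adjusted p = 0.0585 to 0.0604 and 0.0846 to 0.0876). The mural cell list had 1 lower gene of 5, Acta2 at -0.80, or 3 adjusted over the list alone (camera adjusted p = 0.00623, and adjusted p = 0.106 with an estimated correlation). With fry, a test of whether a list moves on balance one way, the adjusted p was 0.0533 for the secretion list. Over the 30 lists, 11 passed camera with the preset correlation and 5 with an estimated one. Other splits of the 12 libraries also gave many lists with the preset correlation, up to 17, or up to 12 where the split mixed the groups evenly.

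The other 19 lists did not pass camera, which asks whether a list moves one way, with camera adjusted p-values from 0.0514 to 0.867. In the proliferation list 0 of 25 genes were called by edgeR, 1 had an unadjusted p under 0.05 and DESeq2 called 0. edgeR called 0 genes in the lists of the hedgehog pathway (12 tested), epithelial to mesenchymal transition (10), immediate early genes (12), posterior lobe pituicytes (7), erythroid cells (5) and leukocytes (11). Of these lists, the hedgehog and immediate early lists had 2 genes each with an unadjusted p under 0.05 and 1 gene each called by DESeq2, and the others had 0 by either. In the WNT list 3 of 21 genes were higher, Wnt7b (1.26), Sfrp5 (0.58) and Lgr5 (0.48). The call of Sfrp5 was lost without control 1 (edgeR adjusted p = 0.0536). The progenitor list had 2 higher genes of 18, Sox2 and Hes1, and 1 lower, Pitx1 (-0.23). There was 1 called gene in each of the lists for NOTCH (Hes1), FGF (Fgfr3, 0.59), BMP and TGF-beta (Tgfb2, 0.30), fibroblasts (Pdgfra, 0.43), cartilage and bone (Runx2, 0.31), Schwann cells (Erbb3, 0.32), endothelium (Plvap, -0.26), corticotropes (Neurod1, -0.53) and melanotropes (Pax7). The call of Hes1 (0.15) was lost without any library but control 5 and mutant 5, that of Pitx1 without control 1, 3 or 4 or mutant 1 to 5, and that of Plvap without control 0 or 3 or mutant 0, 3, 4 or 5, at edgeR adjusted p-values up to 0.107, 0.0804 and 0.0664. With limma at 4 pseudocounts the calls of Tgfb2 (adjusted p = 0.0695 to 0.073), Runx2 (0.123 to 0.144) and Hes1 (0.197 to 0.198) were lost. Without the 3 libraries with high Xist those of Runx2, Hes1, Fgfr3, Lgr5, Sfrp5, Pdgfra, Pitx1, Plvap and Stmn2 were lost (edgeR adjusted p = 0.0568 to 0.186). Lists passed with single libraries left out: WNT without control 0 or 3 or mutant 1 or 3 (camera adjusted p down to 0.0242), fibroblasts without control 0 or 3 or mutant 3 or 4 (down to 0.00322), Schwann cells without control 3 or mutant 0, 2 or 3 (down to 0.00331), and pituicytes without control 3 (0.03). The fibroblast list also passed in 10 of 20 other alternatives (camera adjusted p = 0.0173 to 0.0483), limma at 4 pseudocounts among them, the Schwann cell list in 8 of 20 (0.0104 to 0.044), again with limma at these, and the hypothalamic neuron list with FPKM of at least 5 (0.0155). These passes rest on the preset correlation: with an estimated correlation over all 12 libraries the adjusted p was 0.49 for WNT, 0.664 for fibroblasts, 0.402 for Schwann cells, 0.668 for pituicytes and 0.87 for hypothalamic neurons. Cartilage and bone passed with fry (adjusted p = 0.000161). The mixed form of fry takes changes in both directions. Of the 19 lists, WNT (adjusted p = 5.28e-09), progenitors (2.36e-05), hypothalamic neurons (0.000948), NOTCH (0.00104) and corticotropes (0.0233) passed it. Endothelium and cartilage and bone did so too (0.0304 each), and the rest did not (0.0664 to 0.899). The hypothalamic neuron list had Stmn2 higher (0.58) and Nefm lower (-0.53). No member of the skeletal muscle list was tested.

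The authors' deposited table marks 661 genes, 540 higher and 121 lower. Of these, 366 passed the level filter used here and all 366 had the same sign. Called here were 313, with 270 higher and 43 lower, where independent lists would share 14.7. The other 295 were not tested here, and without the filter the shared calls came to 532. Both sets of calls come from the same libraries and are not independent. The authors' deposited transcript table marks 624 of 39666 transcripts, and 0 genes had transcripts marked in both directions. The authors' deposited enrichment table lists 279 terms, of which 56 have a Benjamini p under 0.05. Among the terms with the smallest p were extracellular region (92 genes), ion transport (47 genes), epithelial cell differentiation (15 genes) and neuroactive ligand-receptor interaction (21 genes).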

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

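The tests of library swaps, scaling, transcripts and the share of hormone cells were chosen after the result was seen, and that of carried-over tissue after the epithelial result but before its markers were examined.

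An outlying library was sought in 140 groups of 6 values, those of the genes that may be named, and 4 groups had one, where chance gives about 1 in 20. Chgb was lowest in mutant 2, with a gap of 0.722 of the range of its group. Cyp2f2 and Neurod1 were lowest in mutant 5, with gaps of 0.673 and 0.628 of the range. Sec14l3 was lowest in control 2, with a gap of 0.821 of the range.

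Isl1 was higher in the libraries labelled mutant. A swap of libraries between the groups would leave libraries among the other group, and 0 did, which leaves an exchange of the whole groups open. Scaling is argued against by the lowest log2 fold change over 4 other scalings, 0.713. Transcripts of the deleted allele, counted over exons that remain, may add to the level: the authors' deposited transcript table holds 1 transcript of Isl1, pooled over its exons, so this and a change in the cells that express Isl1 cannot be told apart here.

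Epithelial and cilia genes were higher in the libraries labelled mutant. A lower share of hormone cells would raise markers of every other cell type alike. The highest median log2 fold change of the endothelial, leukocyte, mural and erythroid lists was 0.203 (erythroid, 5 tested genes). It was 0.486 or more for the epithelial and cilia lists. Lists of other cells left out of that test had medians of 0.216 (Schwann cell), 0.154 (cartilage and bone) and 0.131 (hypothalamic neuron). The medians were 0.077 for fibroblasts and -0.073 for pituicytes. Nasal or oral epithelium carried over in dissection is a candidate source: of 12 markers fixed for it, 5 reached a mean FPKM of 1 in the libraries labelled mutant, between the bounds set for either reading, and 2 of the 12 are also in the stratified epithelium list. Its most abundant genes were Ltf (4.91 FPKM, and 0.538 in controls), Bpifa1 (3.39, and 0.022 in controls) and Gnal (2.61, and 2.44 in controls). Of the airway secretory markers, Muc5b was at 1.58 against 0.034 in controls, Scgb3a1 at 1.90 against 0.579 and Muc5ac at 0.839 against 0.018. Scgb1a1, an abundant gene of airway secretory cells, was at 0.01 against 0.012. Carried-over tissue and epithelium formed in the gland of this genotype, which was not tested, cannot be told apart here, because both would bring such genes.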

How the results depend on the processing

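DESeq2, edgeR's own filter and the fits without the libraries with high Xist or numbered 0 were chosen after the data were seen. The test on log2(FPKM + 1) with limma was that of the design written before, and became an alternative only once the data were seen to hold counts. The limma alternatives change the test and the values together. The cause of a change was not tested unless given. Isl1 was higher in every alternative run (log2 fold change 0.59 to 0.788). It was not past the threshold at 0.743 with a fold of at least 2, by construction, nor with the exact Wilcoxon test at 0.743 (adjusted p = 0.0506). That test called 0 genes higher, 0 lower and 0 shared with the authors (2944 at an unadjusted p under 0.05). Its smallest possible p, that of fully separated genes, was adjusted to 0.0506, just above the threshold. The simulation cannot judge this test, because too few genes were changed there for its smallest p to pass. Lower genes numbered 214, 215, 216 and 216 with limma at pseudocounts of 0.1, 0.5, 1 and 5, and 807 with DESeq2. Higher and lower genes numbered 425 and 278 after quantile normalization, 148 and 9 with a fold of at least 2, 283 and 192 with FPKM of at least 5 (fewer genes tested), and 379 and 144 without the 3 libraries with high Xist (fewer samples). Calls shared with the authors numbered 532 with no filter, 533 with edgeR's own, 78 with FPKM of at least 5, 152 with a fold of at least 2, and 669 for the authors' q alone. Gene lists changed numbered 5 with an estimated correlation.

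Leaving out 1 library gave 197 to 443 lower genes: 197, 259 and 273 without control 1, 3 and 4, and 237, 211, 239 and 248 without mutant 1, 2, 3 and 4. Of 61 named genes with a call besides Isl1, 53 kept it in all 12 such fits. The 8 others were Sox2, Trhr, Bnip3, Slc2a1, Hes1 (10 of 12 fits lost), Pitx1 (8), Plvap (6) and Sfrp5 (1, without control 1, adjusted p = 0.0536). Over 2251 values of single genes under alternatives, 236 lost a call and 7 gained one, and over 958 of lists 7 and 32. Among the 236 are losses set by the test itself: all calls with the exact Wilcoxon test, and those of smaller folds with the fold minimum.

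The signs that turned were all of uncalled results. Prl was at 0.097 and 0.042 with limma at pseudocounts of 0.1 and 0.5, 0.037 with the replicate block, 0.102 with the Wilcoxon test, and -0.887 to 0.283 over libraries left out (0.283 without control 2). Mean log2 fold changes where the camera direction turned were 0.036 (FGF) and -0.126 (hypothalamic neuron) with no filter, 0.028 (hedgehog) and -0.157 (hypothalamic neuron) with edgeR's own, and -0.005 (progenitor) and 0.039 (hedgehog) with FPKM of at least 5. They were -0.012 (progenitor) after quantile normalization, and for hedgehog -0.028 with the Y-linked covariate, 0 with array weights and -0.041 on ranks. Over libraries left out they ran from -0.07 to 0.011 (melanotrope), -0.061 to -0.015 (hedgehog), 0.007 to 0.081 (FGF) and -0.035 to 0.033 (proliferation). Quantile normalization gave no value for Gh, the highest gene of each library.

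The replicate numbers do not pair the libraries: the same-number correlations were 0.153, 0.058, 0.338, -0.064, -0.036 and 0.045, and not every library correlated best with its own number. The replicate block gave 672 higher and 401 lower genes, and shared 849 of the 1075 calls of the main fit. Under the block Trhr, Bnip3, Hes1, Pitx1 and Plvap lost their calls (edgeR adjusted p = 0.05 to 0.106).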

Other observations

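The tests of the FPKM, both tests of depth and that of Lhb and Fshb were chosen after the result was seen, and the splits were planned, except that those with an estimated correlation were added once the splits with the preset one had been seen.

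Chance is argued against for the counts of genes, though not beyond 1 in 100, the smallest share that the splits drawn can give. Of 100 splits of the 12 libraries into groups of 6, the real one included, 1 gave as many higher genes as the 656 observed, and 1 as many lower genes as the 419 observed. The highest count of the other splits was 48 in a direction. All other splits mixed the groups, so the real difference added to the spread within their groups. The 48 therefore does not measure chance alone. For the 313 calls shared with the authors' deposited table, where 1 split gave as many and the highest other gave 1, the splits decide nothing, since no other split called that many genes at all. For the number of gene lists with the preset correlation chance cannot be excluded: 22 of the 100 splits gave as many as the 11 observed, up to 17. Most of them mixed the groups unevenly and carried part of the real difference, so the 22 does not count chance alone. The split with 17 lists had 4 libraries labelled mutant in 1 of its groups. With 3 libraries labelled mutant in each group the most was 12, which still reaches the 11 observed. With an estimated correlation 1 split gave as many as the 5 observed, and the highest other gave 1.

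The deposited FPKM of control 0 and mutant 0 deviate from their counts: 30.2% and 36.5% of genes were off by over 10%, against 2.37% to 2.73% in the other libraries. Depth is argued against by the other 10 libraries, among them the deepest, whose deviations had an SD of at most 0.074 against 0.152 and 0.168, a test added because a first one did not decide (0 of these libraries lay inside the depth range of their group, at opposite ends). A candidate explanation is that the authors' processing differed for these libraries, since their deviations from the mean of the others correlated across 15117 genes with rho = 0.934 (Pearson's r = 0.753 over 14526 genes against the median library), where the 45 pairs of other libraries, each taken against the mean of the remaining 8, gave rho of 0.056 to 0.149. Genes are not independent replicates, and no biological explanation was tested. Without both libraries 607 genes were higher and 405 lower.

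Lhb and Fshb spread widely within groups, and Lhb was at 72.9 CPM in control 4 against 1.89 to 18.5 in the other controls. In the libraries labelled mutant, Lhb was at 6.16 and 4.31 CPM in mutant 0 and mutant 3 and at 0.736 to 1.095 in the others. A hypothesis is that the sex of the animals may set part of this spread. With the level of Y-linked genes in the model the residual SD fell to 0.581 of its value for Lhb and to 0.695 for Fshb, which lies between the bounds set for either reading, so it stays open with 3 libraries of high Xist.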
